A study of Arabidopsis thaliana with 9 samples.

How the data were processed

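Total RNA of roots was profiled on Affymetrix Arabidopsis Gene 1.1 ST array strips, with 1 array per sample. Per the labels, the plants grew in hydroponics at a pO2 of 11.1 ± 1.1%, each sample pooled 5 plants, and 100 ng of RNA was amplified and labelled with biotin. The deposited values were on the log2 scale, and per the submitters' processing notes they came from Affymetrix Expression Console and RMA, which subtracts background, equalises the distributions of the arrays and condenses the probes of a row into 1 value. Versions and settings of those tools and the genome build were not given in the sources used here. Equalising distributions removes any difference in total signal between arrays, and condensing probes can hide a change that touches part of a gene. Scanner output was not used here, so rows could not be called detected or not, and the quartiles of the row means (1.99, 3.51 and 5.22) show that many rows were dim. The number of arrays limits the precision.

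Rows were named through the platform annotation, with gene names updated by Entrez number through a RefSeq gene table of the TAIR10.1 assembly, which was used for names and for which genes neighbour each other. Of 38408 rows, 16746 were paired with exactly 1 gene, 758 with several and 20904 were not listed in that annotation and stayed unnamed here. Of the named rows, 16601 matched the gene table, and 165 genes had more than 1 row. All rows with 1 gene were tested, and a gene with several rows is named by the row with the highest mean. In all 9 arrays, 30 tested rows held the same values as another tested row, and 7132 did over the whole table. Among the rows tested, 63 were chloroplast-encoded and 88 belonged to AT2G07 loci.

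Groups and replicate numbers came from the sample titles. The fit was made with limma 3.58.1 in R 4.3.3 (lmFit, contrasts and eBayes) over all 9 arrays, 3 per genotype, since so few arrays per group share an estimate of the spread. The contrasts were hcr1-1 against Col-0, hcr1-2 against Col-0, the mean of both alleles against Col-0 and hcr1-2 against hcr1-1. Tests were two-sided, and adjusted p values are Benjamini-Hochberg over the 16746 rows at 0.05, or over the list alone where that is said. No scan date or slide was used here, so no batch could be tested. Single values were also compared by exact permutation of the arrays.

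The 20 gene lists were fixed before the data were examined, as were the tests, the rule for named genes and most of the alternatives. Lists were tested with camera at a preset correlation of 0.01 between genes, with Benjamini-Hochberg adjustment over the lists of a contrast. Camera with an estimated correlation and fry, which tests whether the genes of a list move on balance in 1 direction, were the alternatives. Only the 5 lists with at least 5 measured genes were tested, a minimum set after the coverage was known. The lists covered core hypoxia genes, oxygen sensing, glycolysis and fermentation, aquaporins, potassium, nitrogen, iron, phosphate and sulfur genes, heat shock genes, ethylene, jasmonate, defence and abscisic acid genes, the endodermal barrier, Raf-like kinases, and markers of shoot tissue, root hairs, xylem and dividing cells.

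The named genes were HCR1 first, then the genes past the threshold with no overlap of the arrays, by size. Where fewer passed, the 5 genes per direction with the smallest unadjusted p in a comparison were named as short of the threshold. Up to 4 members per list, and 8 of the core hypoxia list, were named by the smallest p in the mean of both alleles. Members named beyond those, such as AT3G29970, AT3G23170, HRA1 and HRU1, were chosen after their values were seen.

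The test was checked on simulated data with the means and spreads of the real rows and 200 changed genes, in 20 simulations per comparison. In the mean of both alleles it found 54.0% of 1.5-fold, 88.7% of 2-fold and 98.3% of 3-fold changes. That many true changes ease the adjusted threshold, so these rates do not carry over to data with fewer changed genes. The list test was checked with 24 simulated members. In 100 simulations the members shared a factor per array with an SD of 0.55, the size seen in the core hypoxia list, and the genotypes did not differ. The preset correlation made a call in 56% of them, with adjustment over 5 lists. The estimated correlation made a call in 5%, at an unadjusted p under 0.05 for the list alone.

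The alternatives were a fit of the compared groups alone, the replicate number as a block, quantile normalization and median centring of the deposited values, leaving out rows below the median, testing all rows, trended and robust variances, array weights, a fold threshold of 1.5, an adjusted p of 0.1, leaving out each array in turn and the other list tests. Alternatives chosen after seeing the data were the list tests for each allele, fry for the other lists, the glycolysis list without PDC2, and a fit with the core hypoxia mean of each array as a covariate.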

Results

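Root transcript levels were measured in 3 genotypes of Arabidopsis thaliana, the wild type Col-0 and the mutant lines hcr1-1 and hcr1-2, all grown in hydroponics with ample potassium under oxygen shortage (pO2 11.1 ± 1.1%, per the labels). HCR1 (AT3G24715, HYDRAULIC CONDUCTIVITY OF ROOT 1) encodes a Raf-like protein kinase that acts on the water permeability of roots. Each genotype had 3 arrays, and each array was made from 100 ng of RNA of a pool of 5 plants aged 21 days. The labels call the 3 samples of a genotype biological replicates. The deposited values were on a log2 scale, with array medians over all rows from 3.41 to 3.48, and any pair of arrays had a Pearson r across genes of 0.984 to 0.993 (genes are not independent replicates). Of 38408 rows, the 16746 that the array annotation pairs with exactly 1 gene were tested. That annotation left out many well-studied genes, so that 24 of the 48 fixed core hypoxia genes and none of the aquaporins could be examined. All growth was under low oxygen, so the comparisons concern genotype within hypoxia and not the response to hypoxia.

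The mutated gene was examined first. HCR1 signal was 4.78 ± 0.16 (SD, n = 3) in Col-0, 3.02 ± 0.58 in hcr1-1 and 4.30 ± 0.069 in hcr1-2, in log2 units. All 6 mutant arrays lay below all 3 Col-0 arrays. In hcr1-1 the signal stood at 29.6% of Col-0, a log2 fold change of -1.76 (SE 0.23, 95% interval -2.26 to -1.26), and in hcr1-2 it stood at 71.9% of Col-0, a log2 fold change of -0.48 (SE 0.23, 95% interval -0.98 to 0.02). The limma adjusted p for hcr1-1 was 5.43e-05 when adjusted over the list alone (the 7 Raf-like kinases of the HCR1 subgroup) and 0.13 over all genes. For hcr1-2 the values were 0.163 and 0.903. An exact two-sided permutation test of the 6 mutant against the 3 Col-0 arrays gave p = 0.0357, while 3 arrays against 3 cannot go below 0.1. The labels do not place the lesions of the 2 lines, so it is not known here which probes lie outside the disrupted part, and a signal that stays high in hcr1-2 does not measure intact transcript. Of the 6 other kinases of the subgroup, none passed a threshold in any comparison with Col-0. RAF16 (AT1G04700) had log2 fold changes of 0.00 in hcr1-1 and 0.30 in hcr1-2, and RAF35 (AT5G57610) had -0.21 and -0.29. In the mean of both alleles RAF16 stood at 0.15, RAF35 at -0.25 and RAF42 (AT3G46920) at -0.11. The subgroup as a list passed in hcr1-1 (camera adjusted p = 0.0383, adjusted p = 0.49 with an estimated correlation), with a mean of -0.28 that HCR1 carried and a median of 0.00.

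**Figure D1:**
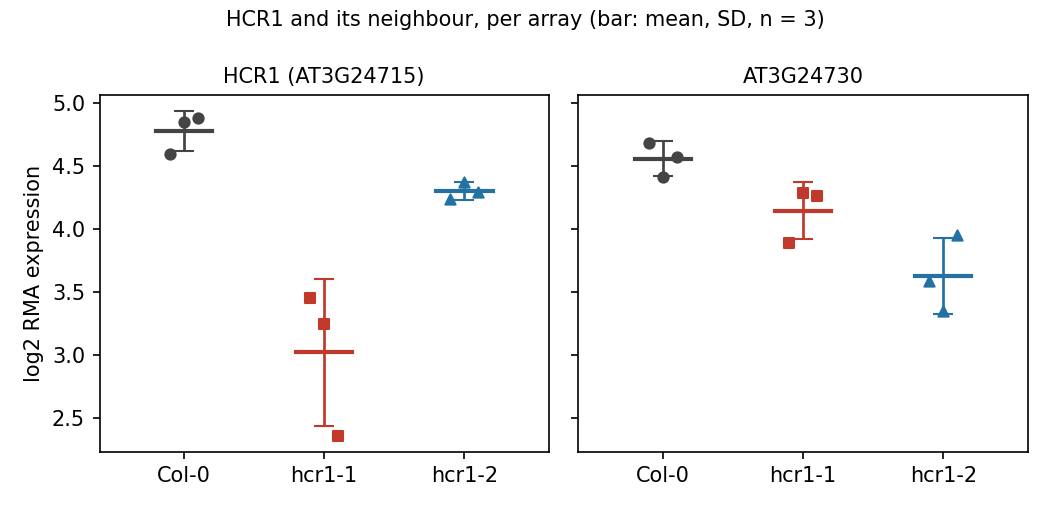
Log2 RMA expression of HCR1 (left) and of the overlapping neighbour AT3G24730 (right) in each array of the 3 genotypes, with the mean and SD as bars (n = 3). HCR1 is lowest in hcr1-1, at a mean of 3.02, while AT3G24730 is lowest in hcr1-2, at 3.63.

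The mean of both alleles against Col-0 asked which root transcripts differed on average over the mutants, so a change in a single allele can drive it. The genes nearest to the threshold, after HCR1 itself, included AT5G35940, a jacalin-related lectin, at a log2 fold change of -1.02 (SE 0.20). AT3G24730, whose gene model overlaps that of HCR1 in TAIR10.1, stood at -0.67 (SE 0.14), AT1G67910 at -0.61 (SE 0.13) and AT2G09970 at -0.46 (SE 0.10). On the higher side stood AT5G43620 at 0.69 (SE 0.13), OCT4 (AT3G20660), an organic cation transporter, at 0.52 (SE 0.12), AT5G42770 at 0.50 (SE 0.12), AT2G46600 at 0.46 (SE 0.11) and AT5G42232 at 0.45 (SE 0.11). In each of these 10 genes, HCR1 included, all 6 mutant arrays lay beyond the range of the Col-0 arrays. Apart from HCR1 they were picked by their smallest p, which favours such a separation, so it adds no support for them. AT2G09970 and AT5G42232 were dim, at 1.47 and 0.88 in Col-0. None of the 10 passed the limma test after adjustment over all genes, where the smallest adjusted p was 0.998. The count of changed genes was 0, with 624 genes at an unadjusted p under 0.05, below the 837.3 that chance alone gives over 16746 rows. The median 95% half-width of a log2 fold change was 0.27. In simulated data with 200 changed genes among 16746, the same test found 54.0% of genes changed 1.5-fold and 88.7% of those changed 2-fold in this comparison. That many changes ease the adjusted threshold, so the rates overstate what would be found among fewer changed genes. Without hcr1-1 replicate 3, 2 genes passed, HCR1 at a log2 fold change of -0.95 and AT5G35940 at -1.17, both with an adjusted p of 0.0448.

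In hcr1-1 against Col-0 the count of changed genes was also 0 by limma, with 542 genes at an unadjusted p under 0.05. With the dimmer rows left out, with trended and robust variances or without hcr1-1 replicate 3, 1 gene passed, which was HCR1 each time. The genes nearest to the threshold on the higher side were AT1G52450 at a log2 fold change of 1.08 (SE 0.22), AT5G43620 at 0.92 (SE 0.15), ARR15 (AT1G74890), a cytokinin-responsive regulator, at 0.64 (SE 0.14), EXLA1 (AT3G45970), an expansin-like wall protein, at 0.63 (SE 0.13), and AT2G07667 at 0.48 (SE 0.10). The last is 1 of 88 rows of AT2G07 loci, which had a median of 0.24 in this comparison. These loci include near-identical copies of organellar genes, so its own signal is uncertain. On the lower side, beside HCR1, stood AT5G35940 at -0.94 (SE 0.23), AT2G09970 at -0.57 (SE 0.12), AT1G75600 at -0.51 (SE 0.12) and AT3G58150 at -0.49 (SE 0.12). Apart from HCR1 and AT5G43620, whose adjusted p over all genes was 0.511, each of these had an adjusted p of 1. In the simulated data 39.9% of genes changed 1.5-fold and 80.7% of those changed 2-fold were found in this comparison. These rates are too high for data with fewer changes. The simulation found 96.5% of 3-fold changes, while the real HCR1 change of 3.38-fold did not pass by limma (adjusted p = 0.13).

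In hcr1-2 against Col-0 the count was 0 by limma, with 904 genes at an unadjusted p under 0.05, and the smallest adjusted p was 0.903. AT3G24730 came first at a log2 fold change of -0.93 (SE 0.17). Below Col-0 stood also AT5G35940 at -1.10 (SE 0.23), AT1G67910 at -0.68 (SE 0.15), AT1G53110 at -0.61 (SE 0.14) and AT3G55790 at -0.54 (SE 0.12). Above Col-0 stood AT2G19050 at 0.79 (SE 0.17), SPO11-1 (AT3G13170), a meiotic recombination protein, at 0.78 (SE 0.15), SCPL32 (AT1G61130), a serine carboxypeptidase-like protein, at 0.67 (SE 0.15), AT4G12545 at 0.61 (SE 0.14) and AT2G16300 at 0.50 (SE 0.11). In each of these 10 genes the 3 hcr1-2 arrays did not overlap the 3 Col-0 arrays. Chance gives that separation to 10% of unselected genes, but these were picked by their smallest p, which favours it, so it adds no support. SPO11-1 and AT2G16300 were dim, at 1.92 and 1.23 in Col-0. In the simulated data 37.1% of genes changed 1.5-fold and 80.0% of those changed 2-fold were found in this comparison, rates that again overstate what would be found among fewer changed genes. The array of hcr1-2 replicate 1 stood apart, with an array weight of 0.47 against 0.79 to 1.47 for the others, and the count without it was also 0.

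The core hypoxia genes, the set that roots and shoots switch on when oxygen runs short, were the group with the widest differences. In hcr1-2 against Col-0, 23 of the 24 measured members had a fitted value below Col-0, with a median log2 fold change of -0.85. In hcr1-1, 22 of 24 lay below Col-0 with a median of -0.47, and in the mean of both alleles all 24 did, with a median of -0.64. The list passed camera with its preset correlation in all 3 comparisons, at adjusted p values of 6.56e-20, 9.22e-08 and 3.32e-18. With an estimated correlation the adjusted p = 0.197 in hcr1-2, the adjusted p = 0.49 in hcr1-1 and the adjusted p = 0.275 in the mean of both alleles, and none of the calls held. The estimated correlation between members was 0.76. The array means of the list, relative to the mean of Col-0, were 0.24, -0.61 and 0.37 in Col-0, -0.07, -1.24 and 0.01 in hcr1-1 and -1.19, -1.07 and -0.52 in hcr1-2, in the order of replicates 1 to 3. An exact two-sided permutation test of these means gave p = 0.155 for the 6 mutant against the 3 Col-0 arrays and p = 0.2 for hcr1-2 against Col-0, where 0.1 is the smallest possible. The mean shifts, -0.44 in hcr1-1, -0.93 in hcr1-2 and -0.68 in the mean of both alleles, stood beside an SD of 0.55 between the arrays of a genotype, and none passed a test that allows for this spread. Without hcr1-1 replicate 2 the median in hcr1-1 was -0.028 (camera adjusted p = 0.476), with Col-0 replicate 2, itself at -0.61, kept. Each hcr1-1 array and each hcr1-2 array lay below the Col-0 array of the same replicate number. The labels do not say that a number marks a shared batch, and the permutation and list tests above did not pair by it.

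In hcr1-2, 14 of the 24 passed adjusted over the list alone, all of them lower than in Col-0, while 0 passed over all genes tested, 19 had an unadjusted limma p under 0.05 and 7 had all 3 hcr1-2 arrays below all 3 Col-0 arrays. In hcr1-1, 1 of the 24 had all 3 arrays below Col-0. Chance gives 5% for independent genes, which these were not. In hcr1-1 the count over the list alone was 0, and in the mean of both alleles it was 1, AT1G10140, at a log2 fold change of -0.57 (SE 0.14) with an adjusted p of 0.0354 over the list. The largest differences in hcr1-2 belonged to AT5G10040 at -2.23 (SE 0.72), AT3G29970 at -1.72 (SE 0.67) and AT3G23170 at -1.66 (SE 0.55), of which AT5G10040 stood at -1.56 in the mean of both alleles. CML38 (AT1G76650), a calmodulin-like calcium sensor, had -1.57 (SE 0.50) in hcr1-2 and -0.79 (SE 0.50) in hcr1-1. HRU1 (AT3G03270), a universal stress protein, had -1.23 and -0.55, and HRA1 (AT3G10040), a transcription factor that restrains the hypoxia response, had -1.05 and -0.49. In the mean of both alleles AT5G42200 stood at -0.62, AT5G26200 at -0.69, AT2G15880 at -0.98, AT4G27450 at -0.65 and AT3G27220 at -0.63, with unadjusted limma p values from 0.0119 to 0.0296.

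**Figure D2:**
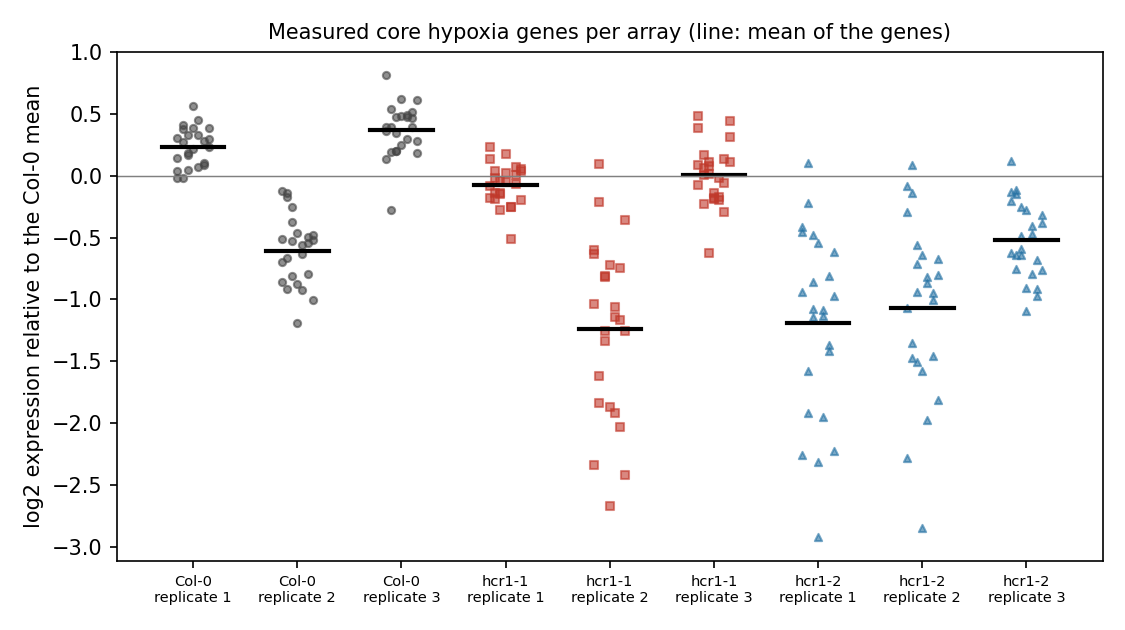
Log2 expression of the 24 measured core hypoxia genes in each of the 9 arrays, relative to each gene's mean in Col-0; points are genes and the black line is their mean. The means run from 0.37 in Col-0 replicate 3 to -1.24 in hcr1-1 replicate 2, and Col-0 replicate 2, at -0.61, lies below hcr1-2 replicate 3, at -0.52.

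The glycolysis and fermentation list had 7 measured members out of 23. AlaAT1 (AT1G17290), an alanine aminotransferase of hypoxic nitrogen metabolism, had a log2 fold change of -1.07 (SE 0.35) in hcr1-2 and -0.45 (SE 0.35) in hcr1-1. LDH1 (AT4G17260), the lactate dehydrogenase, had -0.46 and -0.29, and PDC2 (AT5G54960), a pyruvate decarboxylase that is also on the core hypoxia list, had -0.61 and -0.26. GAPC2 (AT1G13440) had -0.22 and -0.07. AlaAT1 followed the array mean of the core hypoxia list (Pearson r of 0.99 over the 9 arrays), so its shift was not separate from that list. Its exact two-sided permutation p was 0.2 in hcr1-2 against Col-0. None of the 7 glycolysis and fermentation members passed adjusted over their list alone. The list as a whole passed camera in the mean of both alleles with a median of -0.14 (adjusted p = 0.0174, adjusted p = 0.275 with an estimated correlation) and in hcr1-2 (adjusted p = 0.0107, adjusted p = 0.197 with an estimated correlation). In hcr1-1 its adjusted p was 0.149. Left without PDC2, the list had an adjusted p of 0.0511 in the mean of both alleles, where its mean went from -0.22 to -0.19 and its median from -0.14 to -0.075. The list was not tested without AlaAT1.

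The iron deficiency list had 6 measured members out of 29, of which 5 lay above Col-0 in the mean of both alleles. S8H (AT3G12900), which makes the iron-mobilising coumarin fraxetin, stood at 0.93 (SE 0.28) there and at 1.21 (SE 0.33) in hcr1-2, and it passed adjusted over the list alone in both (adjusted p 0.0417 and 0.0204) but not over all genes. The small peptides IMA1 (AT1G47400) and IMA2 (AT1G47395), which act early in iron signalling, had 0.47 and 0.69 in the mean of both alleles. PYE (AT3G47640), a transcription factor of the same response, went the other way at -0.35. The list passed camera in the mean of both alleles at an adjusted p of 0.0474 with a median of 0.28, but at an adjusted p = 0.314 with an estimated correlation, and its adjusted p was 0.149 in hcr1-1 and 0.0678 in hcr1-2.

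The heat shock and chaperone list had 10 measured members out of 29, and 9 of them lay below Col-0 in hcr1-2 with a median of -0.22. HSP23.5 (AT5G51440), a small mitochondrial heat shock protein, had -0.80 (SE 0.33) in hcr1-2 and -0.29 in hcr1-1. ROF2 (AT5G48570), a heat-induced immunophilin, had -0.48 and -0.01. In the mean of both alleles HSP17.8 (AT1G07400) stood at -0.35 and HSP17.6C (AT1G53540) at -0.24. HSP17.8 was dim, at a mean of 1.78 over the 9 arrays. No member passed adjusted over the list alone. The list passed camera in hcr1-2 (adjusted p = 0.00185, adjusted p = 0.197 with an estimated correlation) and in the mean of both alleles (adjusted p = 0.0153, adjusted p = 0.314 with an estimated correlation), and not in hcr1-1 (adjusted p = 0.276).

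The other 15 lists had 0 to 4 measured members each and were read gene by gene. The potassium transport list was represented by KUP12 (AT1G60160), with log2 fold changes of -0.48 (SE 0.12) in hcr1-2 and -0.17 (SE 0.12) in hcr1-1. As its only measured member it had an unadjusted limma p of 0.00239 in hcr1-2, and 0.903 after adjustment over all genes. In the mean of both alleles the sulfur list held SDI2 at -0.24, BGLU28 at 0.18, APS3 at -0.12 and SIR at 0.00. The ethylene list held EIN3 at -0.19, RTE1 at 0.15 and ACO3 at 0.02, and the jasmonate list held JRG21 at 0.24 and OPCL1 at -0.04. PDF1.2 of the defence list stood at 0.02, and the abscisic acid list held COR15A at -0.25, KIN1 at 0.10, KIN2 at -0.05 and COR47 at 0.00. Of the endodermal barrier genes GSO1 stood at 0.26, SGN1 at -0.18 and FACT at -0.14. The few cell type markers measured were, in the mean of both alleles, the shoot genes RCA at -0.11 and LHCB4.1 at 0.02, the root hair genes EXPA18 at 0.20 and EXPA7 at 0.03, the xylem gene GUT2 at -0.20 and the mitotic kinases AUR2 at 0.28 and AUR1 at -0.05. None of these passed over all genes. In hcr1-2 AUR2 stood at 0.39 and passed adjusted over its list of 2 measured genes (adjusted p = 0.0431), and EXPA18 stood at 0.37. In hcr1-1 GUT2, alone on its list, stood at -0.25 with an unadjusted limma p of 0.0472. No member of the oxygen sensing, aquaporin, nitrogen or phosphate lists was on a tested row.

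**Figure D3:**
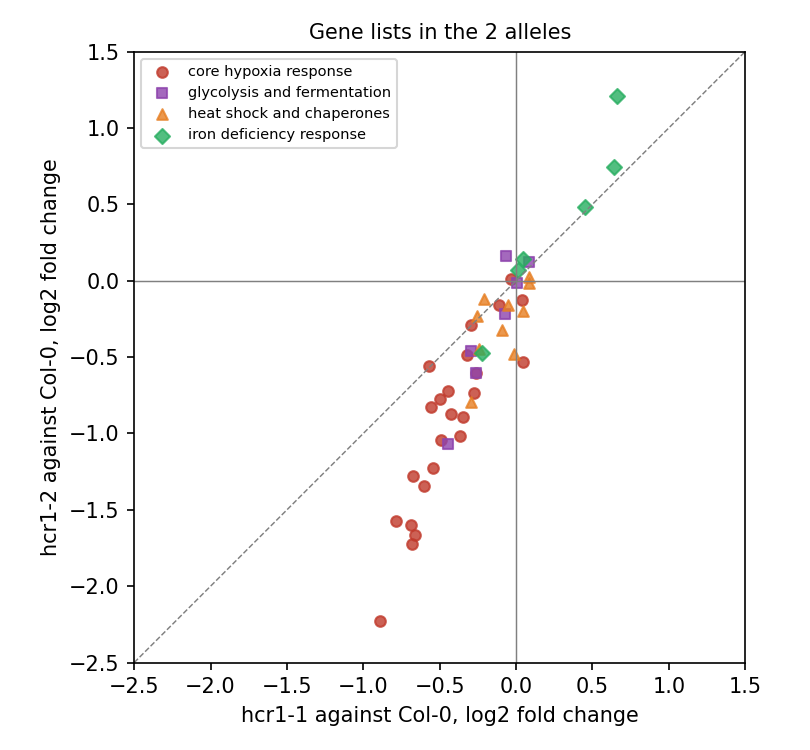
Log2 fold change against Col-0 in hcr1-1 (horizontal) and hcr1-2 (vertical) for the measured genes of 4 lists; each point is 1 gene and the dashed line marks equal values. Most core hypoxia genes lie in the lower left below the dashed line, down to -2.23 in hcr1-2, and S8H reaches 1.21.

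The 2 alleles were also set against each other. By limma 0 genes differed between hcr1-2 and hcr1-1 after adjustment, with 893 at an unadjusted p under 0.05 and a smallest adjusted p of 0.719. HCR1 was higher in hcr1-2 by 1.28 (SE 0.23), which passed adjusted over the list alone (adjusted p = 0.000979). Next on that side stood AT1G44030 at 0.93 (SE 0.17), AT1G49180 at 0.81 (SE 0.17), AT3G47050 at 0.76 (SE 0.16) and AT3G27490 at 0.70 (SE 0.13). On the other side stood AT5G39150 at -1.02 (SE 0.22), AT4G07940 at -0.72 (SE 0.15), AT2G07722 at -0.67 (SE 0.14), AT1G56120 at -0.64 (SE 0.12) and AT3G28820 at -0.62 (SE 0.11). AT2G07722 is among the AT2G07 loci, which include near-identical copies of organellar genes, so its signal is uncertain. AT5G39150 and AT3G28820 were dim, at 1.12 and 1.16 in hcr1-2.

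No gene passed the threshold the same way in both alleles, by limma over all genes. Across genes the fold changes of the 2 alleles had a Pearson r of 0.46 and a covariance of 0.0127, and 64.7% of rows had the same sign. Because both comparisons use the same 3 Col-0 arrays, unchanged groups simulated against such controls already gave a mean r of 0.50 (0.47 to 0.52 in 100 simulations), a covariance of 0.0146 (0.0135 to 0.0157) and 66.6% of rows with the same sign (66.1% to 67.8%). All 3 observed values lay below the lowest simulated one. The simulation treated genes as independent and gave every array the same spread, while the array weights ran from 0.47 to 1.47. It therefore cannot say whether the alleles shared more or less than unchanged groups would. Of the 24 core hypoxia genes, 21 lay below Col-0 in both alleles, and part of that accord may come from the shared controls, which were too few to be divided.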

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

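All the explanations weighed here were set out after the values had been seen, and for a count of 0 the outcome of a test of splits is fixed in advance.

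HCR1 differed between the alleles, with hcr1-2 above hcr1-1 by 1.28 on the log2 scale and an adjusted p of 0.000979 over the 7 kinases of its list by limma. The core hypoxia list differed between the alleles by a median of -0.51 (hcr1-2 minus hcr1-1; camera adjusted p = 3.63e-06, adjusted p = 0.374 with an estimated correlation). That median was -0.28 without hcr1-1 replicate 1, -0.29 without hcr1-1 replicate 3 and -0.82 without hcr1-1 replicate 2. The heat shock and chaperones list differed by a median of -0.16 (camera adjusted p = 0.0356, adjusted p = 0.374 with an estimated correlation).

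The lower core hypoxia signal in mutant roots was weighed against variation between root pools. Within genotypes the mean of the list varied with an SD of 0.55 between arrays, above all of 10000 expression-matched random lists (median 0.04, highest 0.11). A difference of the list mean as large, in either direction, was given by 13 of the 84 splits of the 9 arrays into 6 and 3, so pools that differed in oxygen state or handling may account for it without any effect of genotype. These splits took no account of replicate number, and the labels do not say whether a number marks a shared batch. Each mutant array lay below the Col-0 array of the same number. An effect of hcr1 remains open too: 3 of the 6 mutant arrays lay below all Col-0 arrays, 2 of them from hcr1-2, which is too few to decide. With 3 pools per genotype and this spread, the arrays do not decide between the 2.

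AT3G24730, whose gene model overlaps that of HCR1, had a log2 fold change of -0.41 in hcr1-1 and -0.93 in hcr1-2. Chance stays open, since its limma adjusted p over all genes was 0.903 in hcr1-2, a value that many genes shared. Its unadjusted limma p of 0.000154 was the smallest there. The adjusted p takes no account of its position beside HCR1. Over its group of 22 measured neighbours of HCR1, chosen after the values were seen, the adjusted p was 0.00338 in hcr1-2 and 0.35 in hcr1-1. The shift of the core hypoxia list is argued against as the whole source, because with the list mean as a covariate the fold change in the mean of both alleles was -0.61 (SE 0.18), against -0.67 without it. Signal shared with HCR1 stays open: AT3G24730 was lower in hcr1-2 than in hcr1-1 by a log2 value of -0.52 (SE 0.17), opposite to HCR1, but an allele could disrupt the overlapping part alone, a limit added once the overlap was noticed. A local effect of the lesions on the neighbouring gene was not tested, as their positions were not used here.

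The counts of genes were set against other splits of the arrays. For the mean of both alleles all 84 splits gave at least the real count of 0, the highest other split gave 3, and 64 of the 84 gave at least the 610 genes at an unadjusted p under 0.05 of the real split (a limma fit of 2 groups), with a highest of 2098. The first says nothing about chance, since no split can give fewer than 0, and chance cannot be excluded for the second. The highest split called several times the real number, which may reflect a structure of the arrays other than genotype, although no table compares it with unstructured arrays. For each allele against Col-0 and between the alleles, the 10 splits are too few for a share under 0.05, and the real count and the highest other were both 0. For genes changed the same way in both alleles, all 100 splits examined gave 0, as did the real one, which likewise says nothing about chance.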

How the results depend on the processing

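The fits with a core hypoxia covariate, the list tests for each allele, fry for the other lists and the list without PDC2 were chosen after seeing the data. The count for hcr1-1 against Col-0 was 0 in the reported fit and 1 with rows below the median left out and with trended and robust variances, the gene being HCR1. Leaving out each array gave 0 to 1 for hcr1-1 and 0 to 2 for the mean of both alleles, the higher values without hcr1-1 replicate 3. Every other alternative run gave 0 for each comparison, the core hypoxia covariate included. The core hypoxia median kept its sign under all alternatives run. Its call was lost with an estimated correlation and with fry at unchanged medians of -0.47 in hcr1-1, -0.85 in hcr1-2, -0.64 in the mean of both alleles and -0.51 between the alleles, because these tests allow for the correlation of its members (fry adjusted p = 0.611, 0.293, 0.275 and 0.507). Without each array in turn the medians ranged from -0.73 to -0.028 in hcr1-1, -1.10 to -0.64 in hcr1-2, -0.92 to -0.45 in the mean of both alleles and -0.82 to -0.28 between the alleles. The call in hcr1-1 was lost without hcr1-1 replicate 2 (adjusted p = 0.476). Of 641 refits of the 41 named values of single genes, 636 kept their side of the threshold, 5 passed it and 0 changed sign. Over all tested rows, 2 of 9 same-numbered pairs of arrays had deviations correlated above 0.1 (-0.19 to 0.16). That does not settle pairing for the core hypoxia list. Its mean was highest in replicate 3 of each genotype (0.37 in Col-0, 0.01 in hcr1-1 and -0.52 in hcr1-2). Its lowest mean was in replicate 2 of Col-0 and hcr1-1 but in replicate 1 of hcr1-2. With the replicate number as a block each count was 0 and the core hypoxia median in the mean of both alleles was -0.64, with its preset-correlation call unchanged. That call carries little weight, since the preset correlation also made it in 56% of simulations without a genotype effect. Dim rows limit what the arrays could show.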

Other observations

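The tests here were chosen after the values had been seen. A small set of genes outside the core hypoxia list followed its level from array to array within genotypes. In a limma fit with genotype and the array mean of the list, 12 of 16722 rows passed with a positive slope after Benjamini-Hochberg adjustment and 0 with a negative one. At an unadjusted p under 0.05 stood 855 rows, near the 837.3 that chance alone gives over 16746 rows. The steepest was AT2G14247, which changed by 1.67 (SE 0.13) on the log2 scale per log2 unit of the list. AT5G10050, next to the list member AT5G10040, had a slope of 1.60, AT3G20395 of 1.32, AT3G48450 of 1.21, AT1G12805 of 1.13 and AT3G60520 of 1.03. AlaAT1, which acts in alanine build-up during oxygen shortage, had 1.02 (SE 0.10). AT4G32480, AT1G03610, AT3G11930, CP5 (AT1G64720) and AT2G36950 had slopes from 0.77 to 0.93.

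No relation of the same level to HCR1 signal was detected, and 9 arrays do not exclude one. The signal in hcr1-2 does not measure intact transcript, so such a relation would not measure HCR1 function either. Over the 9 arrays the list mean and HCR1 had a Pearson r of 0.05 (permutation p = 0.897) and a Spearman rho of 0.37 (permutation p = 0.335), with an r of -0.45 without the 2 farthest arrays and of -0.32 within genotypes. For AT3G24730 the r was 0.65 (permutation p = 0.0635, adjusted 0.127 over 4 relations, AlaAT1 among them) and rho 0.55 (permutation p = 0.134), with an r of 0.36 without those 2 arrays and of 0.20 within genotypes. For S8H the r was -0.25 (permutation p = 0.496) and rho -0.03 (permutation p = 0.949), with an r of -0.10 without them and of 0.46, the opposite sign, within genotypes.

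The 88 rows of AT2G07 loci were singled out after their values were seen and were not tested as a group. Those loci include near-identical copies of mitochondrial genes, but the rows were taken by locus name alone. Their median, relative to Col-0, was 0.35, 0.18 and 0.20 in the 3 hcr1-1 arrays, from -0.05 to 0.04 in the Col-0 arrays and from -0.05 to 0.05 in the hcr1-2 arrays, and 70 of the 88 had a positive fold change in hcr1-1, against 50.9% of all 16746 rows. Of the 63 chloroplast-encoded rows 38 did, with a median of 0.02. The AT2G07 rows share sequence and are not independent.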
